A study of Homo sapiens with 6 samples.

How the data were processed

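Polyadenylated RNA of HuCCT1, an established human cholangiocarcinoma (bile duct cancer) cell line, was sequenced in 6 libraries. Per the labels, 3 libraries (a, b and c) came from wild-type CRISPR clone 1 and 3 (a, b and c) from AQP1 knockout clone 22, both grown in DMEM-F12 with serum. Libraries were made with a stranded TruSeq mRNA kit, per the labels' protocols. Group and letter were taken from the genotype and clone labels. Each genotype is represented by 1 clone, so the comparison of genotypes is also a comparison of clones. The labels do not say that the letters are separate cultures, so p-values measure the spread between these libraries, which may be technical.

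The authors deposited a single table of read counts per gene symbol, with whole numbers and no normalization. Per the submitters' processing notes, Trimmomatic 0.33, FastQC, HISAT2 and edgeR were used and the genome build was hg38. The counting program, its strand setting and the gene annotation are not given in the sources used here. Antisense genes and near-identical copies are therefore reported as uncertain. Of the 26485 rows, 7009 held 0 counts in all 6 libraries. Another 28 rows carried names in the form of spreadsheet dates, with 2 such names on 2 rows each. These rows stayed in library totals and tests but are not named, and they held 0.243 to 0.269% of the counts of a library. No row was a gene of the mitochondrial genome. Gene symbols were matched to RefSeq genes of GRCh38, the same assembly as hg38, which supplied coordinates: 23758 rows matched a current symbol, 1517 an older symbol and 1210 none.

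Library totals were 40536085, 41317113 and 41724447 counts in wild-type libraries a, b and c, and 40827165, 40905209 and 36925338 in knockout libraries a, b and c. A count of 3, taken as the floor, equals 0.0719 to 0.0812 CPM per library, where CPM is a gene's counts per 1000000 counts of its library. Exact 95% intervals and floors cover counting error only, since PCR copies are not independent molecules. Replicates were compared before averaging: over genes with at least 20 counts in a pair, chi-square per degree of freedom was 4.18 to 7.6 in the 6 pairs within groups, so no pair agreed within sampling noise.

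Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM normalization, a quasi-likelihood F test of knockout against wild type over all 6 libraries with no covariate, and Benjamini-Hochberg (BH) adjustment with a threshold of 0.05. This fit tested 14405 genes and left out 12080 rows. The filter removed AQP1, so AQP1 was fitted with the same model after being added back to the tested genes. Standard errors of log2 fold changes were the fold change divided by the square root of F. TMM factors were 0.98 to 1.024.

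Before the data were examined, 40 gene lists with 1094 members were fixed, of which 1079 members were found, and 37 lists had at least 3 tested members. Each was tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, two-sided), with BH adjustment over the 37 lists. Camera with an estimated correlation and fry were run as alternatives. Fry asks whether the genes of a list move on balance in 1 direction and does not compare the list with other genes. The list of mitochondrial genome genes, the aquaporin list and a list of neural and embryonic kidney line markers had too few tested members for camera.

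Named genes followed a rule fixed at the same time. It takes AQP1, a panel of 11 epithelial and mesenchymal genes, the 12 largest fitted rises and 12 largest fitted falls (adjusted p under 0.05, mean CPM of at least 5 in the higher group, groups not overlapping, named protein-coding or noncoding genes without clone-based symbols, Y-linked genes and XIST left out) and up to 4 members of each list. Those members are the 2 largest rises and 2 largest falls that passed. Apart from the most abundant gene of the libraries, a gene outside that rule is said to be so where it is named. Fold bounds for genes at 0 in all libraries of a group use 3 counts over the group.

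Alternatives were RLE factors, library totals alone, no filter, a minimum of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the letters as a replicate block, each library left out in turn, an adjusted p of 0.01 and glmTreat against a 1.5-fold change. The steps were tested on simulated counts for the 14405 genes, with 200 genes changed. At 4-fold, 2-fold, 1.5-fold and 1.25-fold, 100%, 80%, 54% and 56% of 50 genes each were recovered. Of all calls in that simulation, 9.94% were unchanged genes, above the nominal 5%. Far more genes were called in the data than the 200 changed here, so that share does not carry over to those calls. The simulation was first required to recover more than 80% of genes at 2-fold, which a first run did not, and that requirement was then placed at 4-fold. A limit on the share of unchanged genes among calls was added at that point, and 9.94% only just met it. A simulated list shifted 1.5-fold was called by both camera settings, each with 1 call, while fry made 2.

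After the gene table had been seen, the tested genes were also arranged by position. Of them, 97.8% could be placed on chromosomes 1 to 22 or X. Medians were taken in windows of 10 Mb with at least 10 tested genes. A stretch was defined as at least 4 neighbouring windows whose medians had the same sign and a size of at least 0.3. GC content per gene was the median over transcripts in GENCODE v29 and was available for 99.0% of placed genes. Python 3.11.15, scipy 1.17.1 and statsmodels 0.14.6 were used for these steps.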

Results

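RNA sequencing counts were obtained from 6 libraries of HuCCT1, a human cholangiocarcinoma cell line: 3 from a wild-type CRISPR clone and 3 from a clone labelled as AQP1 knockout. AQP1 encodes the water channel aquaporin-1. The libraries held 36925338 to 41724447 counts, with a count in 16476 to 17254 genes each. The 10 most abundant genes took 4.64 to 4.87% of a library, and the most abundant was THBS1 in the wild-type libraries and GAPDH in the knockout libraries. Levels below are mean CPM ± SD with n = 3 libraries per group unless stated otherwise, and fold changes are knockout over wild type.

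The targeted gene had few counts in both clones. AQP1 (chromosome 7, 30911853 to 30925516, GRCh38) had 2, 8 and 10 counts in wild-type libraries a, b and c, and 10, 7 and 7 in knockout libraries a, b and c. These counts correspond to 0.161 ± 0.099 CPM in wild type and 0.202 ± 0.038 CPM in knockout. The ratio of summed counts was 1.25 with a 95% counting interval of 0.66 to 2.39 (exact binomial test, two-sided, p = 0.547). In edgeR's quasi-likelihood test the log2 fold change was 0.27 with an SE of 0.63 and a BH-adjusted p of 0.715, and without wild-type library a it was -0.16. No difference was detectable at this depth. An edited gene need not lose its transcript, so these counts do not check the genotype labels. "Knockout" below means the libraries labelled so. Only 2 other aquaporins on the list were tested. AQP3, which carries water and glycerol, fell from 5.21 ± 0.776 to 1.89 ± 0.282 CPM (log2 fold change -1.51, edgeR quasi-likelihood with BH, adjusted p = 4.74e-06). AQP11, named after its values were seen, did not pass, at 2.17 ± 0.457 and 2.99 ± 0.391 CPM (log2 fold change 0.41, adjusted p = 0.0989 in the same test).

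The title of the series names the epithelial-mesenchymal transition, the loss of epithelial junctions and keratins with a gain of mesenchymal genes. Epithelial genes were far lower in the knockout clone. CDH1, which encodes the junction protein E-cadherin, fell from 202 ± 4.52 to 15.0 ± 1.28 CPM. EPCAM, an epithelial adhesion molecule, fell from 484 ± 6.24 to 40.7 ± 1.41 CPM, and KRT19, a bile duct keratin, from 756 ± 13.8 to 93.5 ± 4.59 CPM. The keratin gene KRT7, on the cholangiocyte list with KRT19 and named outside the rule, changed far less. It went from 1751.3 ± 38.25 to 1613.3 ± 12.5 CPM (log2 fold change -0.17). Mesenchymal genes were higher: the intermediate filament gene VIM rose from 207 ± 6.65 to 835 ± 3.81 CPM and the fibronectin gene FN1 from 103 ± 7.01 to 374 ± 20.6 CPM. Among transcription factors that repress CDH1, ZEB1 rose from 6.25 ± 0.845 to 83.5 ± 1.32 CPM and ZEB2 from 0.526 ± 0.174 to 7.19 ± 0.428 CPM.

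In log2 terms CDH1 changed by -3.80 (SE 0.047, adjusted p = 3.47e-16), EPCAM by -3.63 (SE 0.032) and KRT19 by -3.07 (SE 0.035) in edgeR's quasi-likelihood test with BH adjustment. VIM changed by 1.96 (SE 0.028), FN1 by 1.80 (SE 0.049), ZEB1 by 3.69 (SE 0.080) and ZEB2 by 3.71 (SE 0.214). Smaller rises were seen for CDH2, the neural cadherin gene, at 0.56 (SE 0.024), for SNAI1 at 0.56 (SE 0.162, adjusted p = 0.00694) and for SNAI2 at 0.44 (SE 0.042). The tested genes in the 10 Mb window around SNAI2 had a median of 0.55. TWIST1 had 0 counts in all 6 libraries. On GRCh38, CDH1 lies on chromosome 16 (68737292 to 68835537), EPCAM on chromosome 2 (47369311 to 47387020), VIM on chromosome 10 (17228241 to 17237593) and ZEB1 on chromosome 10 (31318417 to 31529804).

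**Figure D1:**
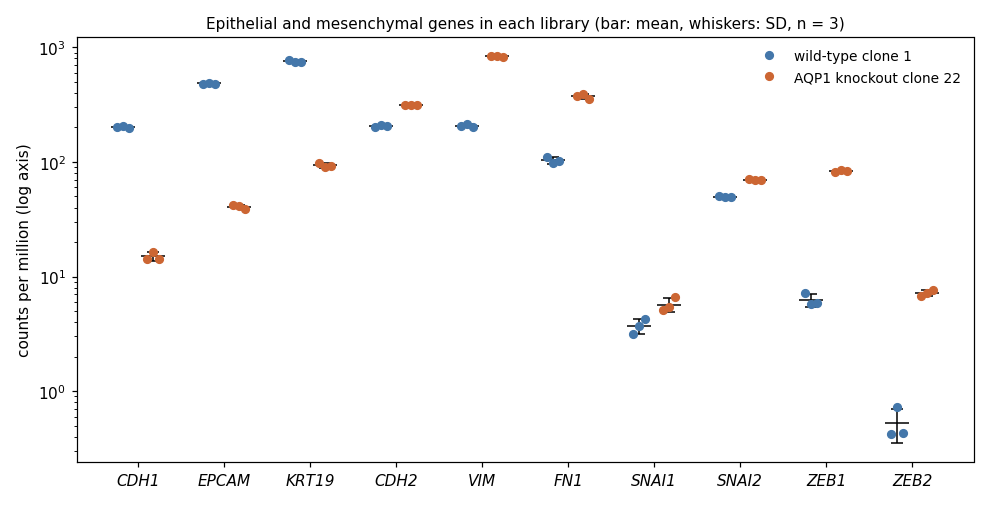
CPM (log axis) of 10 panel genes in each of the 3 wild-type and 3 knockout libraries, with the mean as a bar and the SD as whiskers; TWIST1, at 0 counts, is not drawn. CDH1, EPCAM and KRT19 lie lower and the other 7 genes higher in all 3 knockout libraries than in any wild-type library.

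The epithelial list moved almost as a whole. Of 37 tested epithelial genes, 34 fell, 1 rose and 2 did not pass, counted over all genes, and the same numbers held when adjusted over the list alone. The median log2 fold change was -2.71. ST14, a membrane serine protease of epithelia, fell from 408 ± 3.48 to 9.99 ± 0.980 CPM, and MAL2, which serves apical membrane transport, from 716 ± 12.4 to 19.1 ± 2.24 CPM. The gene that rose was TJP3, at 0.220 ± 0.154 and 0.642 ± 0.265 CPM, and its call was lost without wild-type library c (adjusted p = 0.101) or knockout library c (adjusted p = 0.131). Camera gave a BH-adjusted p of 1.36e-14, and adjusted p = 0.11 with an estimated correlation.

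Of 31 mesenchymal genes, 25 rose, 2 fell and 4 did not pass, also when adjusted over the list alone, with a median of 1.43. TNC, which encodes the matrix protein tenascin C, rose from 0.155 ± 0.088 to 38.8 ± 1.76 CPM. TNC, and BGN at 0.008 CPM in wild type, could pass the filter only through the knockout libraries. For such genes a rise was built in. The median wild-type level of the list was higher, at 5.56 CPM. The falls were in TAGLN (5.56 ± 0.199 to 2.28 ± 0.402 CPM) and CALD1 (201 ± 1.00 to 145 ± 0.546 CPM), both genes of the contractile cytoskeleton. The camera test of the mesenchymal list gave a BH-adjusted p of 7.68e-07, and adjusted p = 0.117 with an estimated correlation. It was not repeated without genes such as TNC and BGN. The list of epithelial-mesenchymal transcription factors was not called (camera, BH-adjusted p = 0.121), although 8 of its 13 genes rose and 3 fell over all genes, and 9 rose and 3 fell when adjusted over the list alone. TCF4 fell from 2.89 ± 0.211 to 0.924 ± 0.176 CPM.

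Junction genes and keratins followed the epithelial genes with which they share members (3 each). Of 30 claudin and junction genes, 16 fell, all by at least 2-fold, 8 rose and 6 did not pass, also adjusted over the list alone, and the median was -1.05. CLDN9 fell from 4.48 ± 1.11 to 0.267 ± 0.145 CPM. CGNL1, a tight junction linker gene, rose from 0.679 ± 0.190 to 3.64 ± 0.827 CPM. The call of this list (camera, BH-adjusted p = 0.0444) was lost without wild-type library a (0.0626), b (0.0636) or c (0.0649), without knockout library c (0.0784), under a 1 CPM minimum (0.0625), and with an estimated correlation (adjusted p = 0.212). Of 12 keratin genes, 8 fell and 2 rose, also adjusted over the list alone. KRT17 fell from 18.9 ± 1.12 to 2.87 ± 0.371 CPM, while KRT5, a basal keratin, rose from 0.307 ± 0.058 to 1.41 ± 0.355 CPM. The keratin list had a camera BH-adjusted p of 0.00477, and adjusted p = 0.141 with an estimated correlation.

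Cholesterol synthesis genes were lower throughout. All 25 tested genes of sterol synthesis and uptake fell, over all genes and adjusted over the list alone, 17 of them by at least 2-fold, with a median of -1.21. INSIG1, a sterol-responsive regulator of the pathway, fell from 104 ± 5.09 to 11.3 ± 0.478 CPM. HMGCS1, which makes the substrate of the mevalonate pathway, fell from 274 ± 0.075 to 48.0 ± 3.93 CPM. Of 16 fatty acid synthesis genes, 14 fell and none rose, with the same numbers adjusted over the list alone. FASN, the fatty acid synthase gene, fell from 366 ± 20.8 to 106 ± 1.04 CPM and the desaturase gene SCD from 419 ± 2.29 to 158 ± 2.14 CPM. Camera gave the sterol list a BH-adjusted p of 4.66e-11 (adjusted p = 0.11 with an estimated correlation) and the fatty acid list 6.37e-05 (adjusted p = 0.117 with an estimated correlation).

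Glycolytic and hypoxia-responsive genes were mostly higher. Of 34, 28 rose and 2 fell, also adjusted over the list alone, with a median of 0.41. CA12, a carbonic anhydrase gene, rose from 4.54 ± 0.245 to 52.1 ± 2.63 CPM and the glucose transporter gene SLC2A3 from 11.8 ± 0.948 to 76.0 ± 2.77 CPM. The 2 that fell are SLC2A1, another glucose transporter gene (265 ± 8.08 to 121 ± 1.87 CPM), and the hexokinase gene HK2 (107 ± 4.76 to 51.3 ± 1.87 CPM). Of 25 NRF2 target genes, which serve oxidant defence and detoxification, 17 rose and 4 fell, also adjusted over the list alone. ALDH3A1 rose from 0.444 ± 0.182 to 21.3 ± 0.174 CPM and the export pump gene ABCC3 from 7.26 ± 0.702 to 95.7 ± 1.78 CPM. Of 26 TGF-beta target genes, 18 rose and 4 fell, also adjusted over the list alone. TGFBI, a secreted matrix protein gene, rose from 295 ± 2.16 to 2723 ± 32.4 CPM, and BAMBI, a decoy receptor gene, from 0.544 ± 0.325 to 9.58 ± 0.849 CPM. SMURF2 fell from 408 ± 9.90 to 111 ± 4.37 CPM. BH-adjusted camera p-values were 1.95e-06 for glycolysis and hypoxia, 0.00143 for NRF2 and 0.00207 for TGF-beta. With an estimated correlation these became adjusted p = 0.117, 0.282 and 0.282.

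Of 30 G1/S genes 19 fell and 5 rose, also adjusted over the list alone, with a median of -0.27 (camera, BH-adjusted p = 0.00455; adjusted p = 0.282 with an estimated correlation). CDC6, which licenses replication origins, fell from 207 ± 2.11 to 100.2 ± 1.79 CPM, and TYMS, the thymidylate synthase gene, rose from 34.0 ± 2.14 to 105 ± 1.78 CPM. Of 33 G2/M genes, 14 rose and 14 fell, none by 2-fold, and the list was not called (camera, BH-adjusted p = 0.7). Whether the lists for G1/S and G2/M differ was not tested. Of 51 primary cilium genes 32 rose and 10 fell (camera, BH-adjusted p = 0.0164; adjusted p = 0.141 with an estimated correlation). IFT27 rose from 1.06 ± 0.332 to 5.16 ± 0.372 CPM, and NEDD9, a scaffold gene, fell from 37.1 ± 1.42 to 11.6 ± 1.18 CPM. Of 34 ribosomal protein genes 22 rose and 8 fell, none by 2-fold (camera, BH-adjusted p = 0.02; adjusted p = 0.676 with an estimated correlation). RPL4 on chromosome 15 rose from 1155 ± 10.8 to 2176 ± 82.9 CPM and RPS14 on chromosome 5 from 271 ± 10.5 to 474 ± 23.1 CPM; both lie in stretches of raised genes. Counts adjusted over the list alone were the same for the G2/M, cilium and ribosomal lists.

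Markers of other cell types were measured in both clones, and some moved with the groups. Of 23 hepatocyte genes only 7 were tested, and of these 6 rose and none fell. Camera gave the list a BH-adjusted p of 0.0117, and adjusted p = 0.178 with an estimated correlation. The median log2 fold change of the 7 was 4.98, and 3.68 with 2 genes that had 0 counts in wild type set at their bound. Their median level was 0.0403 CPM in wild type and 2.23 CPM in knockout. Genes this near 0 in wild type could pass the filter only through the knockout libraries, so for them a rise was built in. The camera call is therefore no separate support. The fibrinogen genes FGB (0.040 ± 0.014 to 15.6 ± 1.09 CPM) and FGA (0 to 2.23 ± 0.326 CPM) led the rises. Of 10 fibroblast genes 6 rose and 1 fell, which was FBLN1 (227 ± 7.22 to 83.2 ± 2.60 CPM), and the list, which shares 12 members with the mesenchymal list, was not called (camera, BH-adjusted p = 0.121). Adjusted over the list alone, the hepatocyte and fibroblast counts were the same. Of 5 transcripts abundant in fibroblasts, the matrix proteoglycan genes LUM (5.33 ± 0.616 to 17.4 ± 0.675 CPM) and DCN (0.032 ± 0.055 to 0.907 ± 0.138 CPM) rose. The collagen gene COL1A1 (9.89 ± 0.589 and 9.07 ± 2.10 CPM) did not pass, and COL1A2 (0.048 ± 0.048 and 0 CPM) and COL3A1 (0.016 ± 0.014 and 0.057 ± 0.051 CPM) were too low to be tested. These 5 were chosen after their values were seen. Endothelial, immune and intestinal or pancreatic lists were not called by camera, with BH-adjusted p of 0.561, 0.645 and 0.709. The neuronal microtubule gene MAP2 rose from 3.76 ± 0.099 to 18.1 ± 0.856 CPM. Of 19 cholangiocyte genes 6 rose and 11 fell, and 12 fell when adjusted over the list alone (camera, BH-adjusted p = 0.241). SPP1 (osteopontin) rose from 0.291 ± 0.047 to 11.4 ± 1.01 CPM and PKHD1, a polycystic disease gene, fell from 8.92 ± 0.435 to 0.561 ± 0.124 CPM.

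In total 13 of 37 lists were called by camera with the preset correlation, 0 with an estimated correlation and 37 by fry. Lists not called often held large changes in both directions. Among collagens and laminins, COL5A2 rose from 23.6 ± 0.774 to 313 ± 6.37 CPM and COL4A4, a basement membrane collagen gene, fell from 65.0 ± 1.75 to 3.41 ± 0.770 CPM. Among integrins, ITGB3 rose from 0.081 ± 0.058 to 8.81 ± 0.364 CPM and ITGB6, an epithelial subunit, fell from 15.8 ± 0.593 to 2.51 ± 0.386 CPM. Among inflammatory genes, CSF1 rose from 58.2 ± 3.01 to 401 ± 6.82 CPM and LCN2 fell from 74.8 ± 3.72 to 3.49 ± 0.547 CPM. CCND1, the cyclin D1 gene, fell from 1147 ± 21.2 to 469 ± 8.82 CPM. For cell migration and WNT target lists the median or the camera direction differed in sign from the mean; the same was true of biliary ion transporters and of intestinal or pancreatic markers, and the interferon list had a median of 0.

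**Figure D2:**
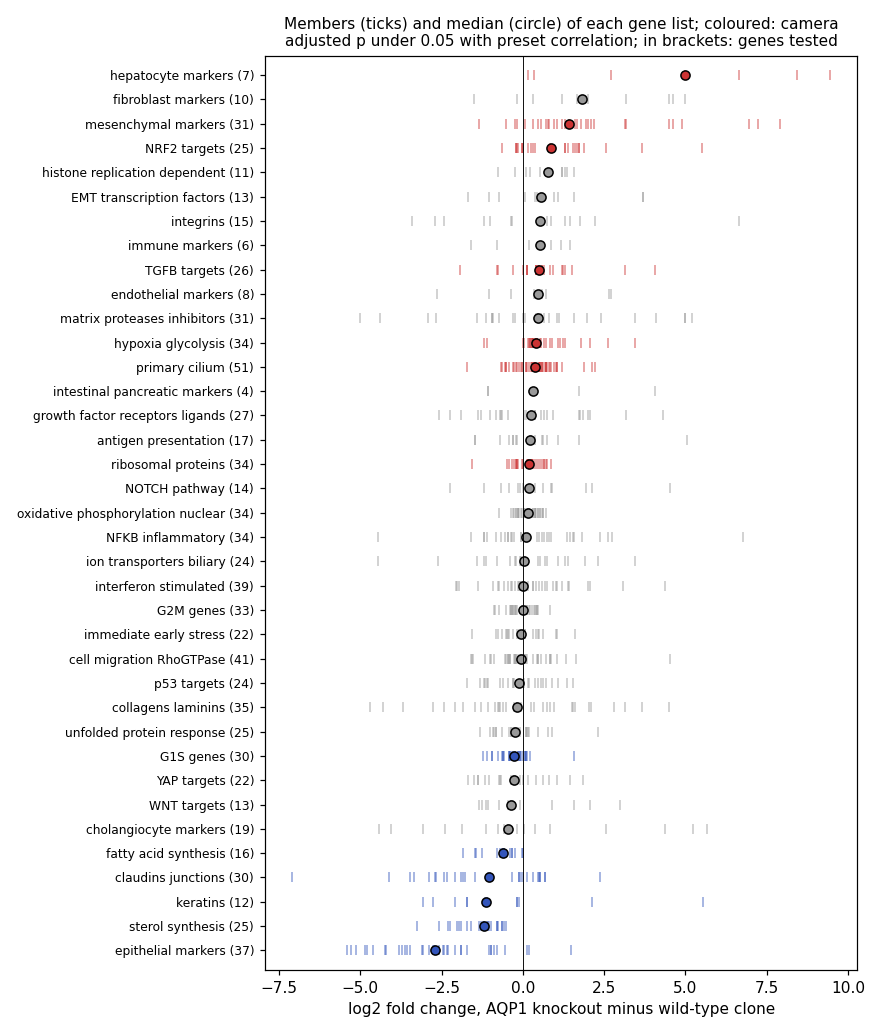
Log2 fold change (knockout minus wild type) of the tested members of 37 gene lists, as ticks, with each list's median as a circle; coloured lists had a camera BH-adjusted p under 0.05 with the preset correlation. The epithelial list has the lowest median, -2.71. The hepatocyte list, with 7 genes at a median of 0.0403 CPM in wild type, has the highest, 4.98.

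Many genes differed between the clones. Of 14405 genes tested, 10711 (74.4%) had an adjusted p under 0.05 in edgeR's quasi-likelihood test with BH adjustment, 5347 higher and 5364 lower in the knockout. Of these, 3279 differed by at least 2-fold (1976 higher, 1303 lower) and 5123 by less than 1.5-fold. At 4-fold or more there were 941 rises and 479 falls. In 11133 genes (77.3%) the groups did not overlap, where chance gives 10%. The common biological coefficient of variation between libraries of a group was 0.0652, so small differences passed.

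The genes with the largest rises had 0 to 2 counts in total in the wild-type clone. LRFN5, a neuronal adhesion gene, had 0 counts in wild type and 32.9 ± 0.778 CPM in the knockout, at least 1360-fold higher. PASD1, a cancer-testis gene on the X chromosome, was at least 792-fold higher (19.2 ± 0.935 CPM) and RTN1 at least 639-fold higher (15.5 ± 0.878 CPM). NAP1L3, MXRA5, STRA6, TAS1R1, ARMCX1, EXO5 and ANKRD30B also had 0 counts in wild type and were at least 460-, 308-, 303-, 277-, 264-, 232- and 229-fold higher. PAGE5 had 2 counts in wild type against 5622, a ratio of 2930 (95% counting interval 810 to 24200), and GNG2 had 1 count against 1054, a ratio of 1100 (197 to 43400).

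The largest falls included RNF212, a meiotic crossover gene, with 21.2 ± 0.254 CPM in wild type and 0 counts in the knockout, at least 837-fold lower. PRDM9, which places meiotic recombination, fell from 39.2 ± 2.91 to 0.049 ± 0.049 CPM. FOXJ1, the regulator of motile cilia, had 1044 counts against 3, a ratio of 334 (95% counting interval 114 to 1620), and DNALI1, a ciliary dynein gene, fell from 8.60 ± 1.03 to 0.041 ± 0.037 CPM. Motile cilium genes did not fall as a family, which was chosen after the results were seen. Of 27 motile cilium dynein and CFAP genes, 9 rose and 9 fell (camera, BH-adjusted p = 0.775). LRRTM4 fell from 56.2 ± 2.12 to 0.167 ± 0.070 CPM, FAM19A2 (now TAFA2) from 12.2 ± 1.10 to 0.033 ± 0.057 CPM, SLC38A5, an amino acid transporter gene, from 16.8 ± 0.251 to 0.142 ± 0.114 CPM, the desmosomal gene DSC3 from 9.21 ± 0.589 to 0.082 ± 0.102 CPM and STEAP4 from 17.4 ± 0.427 to 0.172 ± 0.089 CPM. LINC00639 had 1019 counts against 2, a ratio of 489 (135 to 4050). The antisense genes AFAP1-AS1 (45.3 ± 0.973 to 0.177 ± 0.027 CPM) and MAGI2-AS3 (5.39 ± 0.240 to 0.016 ± 0.028 CPM) are uncertain, since the strand setting of the counting is not stated.

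Neighbouring genes shifted together along whole stretches of chromosomes. On chromosome 5 from 70 to 190 Mb, 85.1% of 436 tested genes were above 0, with a median log2 fold change of 0.59 (bootstrap 95% interval over genes 0.52 to 0.63). Chromosome 15 (452 genes, median 0.47) and chromosome 13 from 20 to 60 Mb (148 genes, median 0.62) were raised. Chromosome 1 from 160 to 230 Mb (359 genes, median -0.67), chromosome 7 from 90 to 130 Mb (211 genes, median -0.63) and chromosome 2 from 120 to 160 Mb (89 genes, median -0.61) were lowered. Chromosome 4 (-0.02), 6 (-0.01), 9 (0.01) and 14 (0.01) had medians near 0. These 6 stretches held 1695 tested genes, of which 83.4% were called, against 73.6% elsewhere. The remainder was not all near 0: of 293 windows, 95 had a median of at least 0.3 in size, some of them outside the stretches. Examples are chromosome 3 from 180 to 190 Mb (-0.913) and 190 to 200 Mb (-0.974), and chromosome 12 from 20 to 30 Mb (0.563). Chromosome 22 had a median of -0.365. The stretches were picked on these same fold changes, so the higher share and the medians away from 0 follow from that choice. The G2/M genes NEK2 and CENPF lie in the lowered part of chromosome 1, ZEB2 in that of chromosome 2, and NUSAP1, CCNB2, STRA6 and CA12 on chromosome 15.

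**Figure D3:**
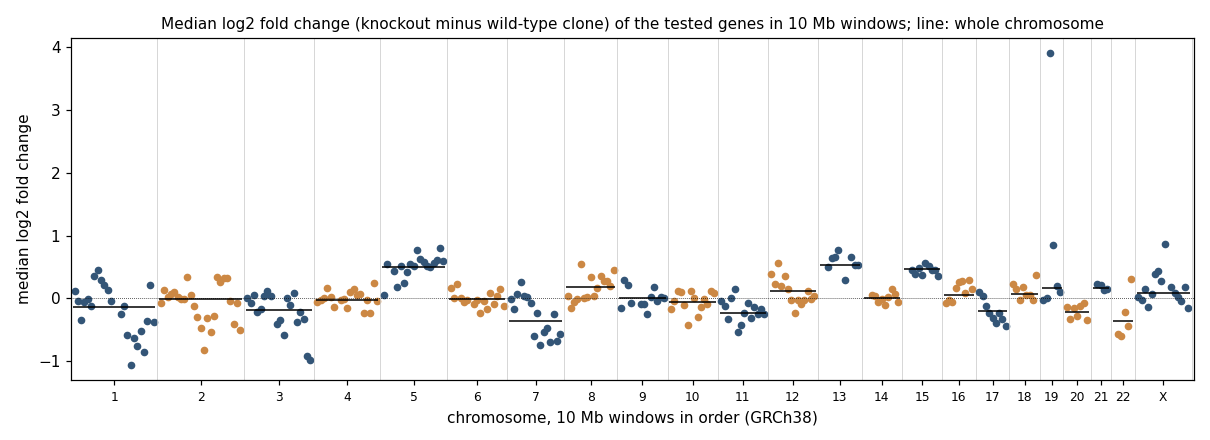
Median log2 fold change (knockout minus wild type) of the tested genes in each 10 Mb window with at least 10 genes, by position on GRCh38, with a line at each chromosome's median. Windows of chromosomes 5, 13 and 15 lie above 0 and those of chromosome 7 from 90 to 130 Mb below; the window of chromosome 19 from 20 to 30 Mb has a median of 3.90.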

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

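The subtraction of window medians was chosen after the results were seen; the other alternatives were planned. No called gene of the 10711 was called in the opposite direction under any of the 13 alternative fits of all genes, and 91.9 to 99.3% of these calls were also made in each. All counts of called genes stayed within 1.5 times: the count at 2-fold was 2560 under a 1 CPM minimum and 2907 after the median of each gene's window was subtracted, and glmTreat, which tests against a 1.5-fold change in place of the 2-fold criterion, called 4354. No clear pairing by letter was seen: deviations of same-letter libraries correlated at 0.058, -0.019 and 0.008, against -0.05 to 0.041 for different letters. Such deviations are mostly noise, so pairing is not excluded. With the letters as a block 10599 genes were called. AQP1 had a log2 fold change of -0.158 to 0.658 when each library was left out, turning negative only without wild-type library a, where it rests on few counts. With an estimated correlation in camera the epithelial list had an adjusted p of 0.11 and the mesenchymal list 0.117. The transcription factor list, not called by camera, had 2.71e-05 by fry, which asks a different question. Estimated correlations of the keratin (-0.062), hepatocyte (-0.062), junction (-0.012) and cilium (-0.009) lists lay below the preset 0.01, yet their calls were lost. A correlation above the preset is thus argued against as the reason for these lists. For the other called lists, with estimates above it, the reason was not tested. Camera with an estimated correlation has few degrees of freedom with 6 libraries. It called a simulated list, but there genes were drawn independently and all genes outside the list were unchanged. That call therefore cannot show its power in these data. The growth factor list turned from up to down by fry (5.15e-05). The biliary ion transporter list, never called by camera, turned direction at adjusted p of 0.877 under a 1 CPM minimum and without wild-type library c or knockout libraries b or c, with 0.88 to 0.995 over the libraries left out in turn. Among 169 gene results named or listed as examples, 31 of the alternatives ended a call and none turned its direction. Genes with few counts in both groups, such as AQP1 with 20 and 24 over 3 libraries each, are limited by depth.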

Other observations

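The tests of gene families, of window medians, of fibroblast transcripts, of GC content over windows, of AQP1 and of splits of the libraries were chosen after the results were seen. Zinc-finger genes of the ZNF series were often higher in the knockout clone: of 455 tested, 218 rose and 96 fell. On chromosome 19, 126 of 216 rose and 27 fell (median log2 fold change 0.59), against 92 and 69 of 239 elsewhere (median 0.11). The window of chromosome 19 from 20 to 30 Mb, with 34 tested genes, had a median of 3.90. Among 16 families taken by symbol the ZNF series had the smallest camera p, and it missed the threshold (adjusted p = 0.0511, and 0.499 with an estimated correlation). Of 23 MAGE, PAGE, GAGE, XAGE, SSX and CTAG cancer-testis genes, whose near-identical copies make single genes uncertain, 13 rose and 8 fell (adjusted p = 0.335). Y-linked genes and XIST were left out of the next counts. At a minimum of 1 CPM in each library of the other clone, 50 genes had 0 counts in all wild-type libraries and 8 in all knockout libraries. Of the 50, 16 were zinc-finger genes (ZNF, ZFP, ZSCAN or ZKSCAN symbols) and 7 lay on the X chromosome. For comparison, the ZNF series made up 455 of the 14405 tested genes, and 507 of the 14092 placed genes lay on X. Whether either count exceeds its share was not tested.

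Stretches of neighbouring genes differed together between the clones. When windows were picked on every other gene, 98 of 110 had the same sign in the remaining genes, and the medians of the 2 sets correlated at 0.822 over 293 windows, against at most 0.225 in 1000 shuffles. GC bias is argued against, since the GC content of a window's genes explained 1.7% of the variance of window medians (bootstrap 95% interval 0.2 to 6.0%). Across single genes, fold changes hardly followed GC content (rank correlation -0.015). A correction of single genes for GC, planned first, therefore moved them by only -0.019 to 0.016. The window medians left after so small a correction add no further test. A difference in chromosome copy number is a candidate explanation: ribosomal protein and nuclear oxidative phosphorylation genes, lists fixed beforehand, followed the median of the other genes in their window with r = 0.607 across 67 genes (rho = 0.714; permutation p = 1e-05 for both, the smallest 100000 permutations can give; r = 0.617 without the 2 farthest genes), where genes are not independent replicates. Copy number itself was not measured, and the chromosome 19 window shows that clustered genes may also shift together by far more than a dosage change of this size.

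The fall of epithelial and rise of mesenchymal genes is hardly a matter of such stretches, since 94.0% of the epithelial median was kept after window medians were subtracted (-2.71 before, -2.55 after, bootstrap 95% interval -3.54 to -2.07). The transcription factor list, which was not called, went from 0.56 to 0.22 (13 genes, bootstrap 95% interval -0.16 to 1.17). That interval also holds 0.56, so how much of its median follows the stretches cannot be told. Fibroblasts mixed into the culture would bring their abundant transcripts, yet COL1A1, COL1A2, COL3A1, DCN and LUM had a median of 0.907 CPM in the knockout libraries, although LUM and DCN rose. Loss of AQP1 and a difference between single clones that arose before or during cloning cannot be told apart, because there is 1 clone per genotype; a different line or passage history of either clone was not tested. The direction of the epithelial and mesenchymal lists is thus a hypothesis about AQP1 that more clones could test. The wild-type clone itself had few AQP1 counts, 20 over its 3 libraries.

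AQP1 counts were low in both clones. Reads lost to an overlapping gene are argued against for the rows that could be placed, since 0 of these other rows overlap the AQP1 locus in RefSeq. The 1210 rows with no match could not be checked, and the annotation used for counting is not given. Swapped labels stay open: the ratio of knockout to wild-type counts was 1.25 with an interval of 0.66 to 2.39, and a swap would give like counts. The libraries labelled wild type did hold little counted AQP1 transcript, at a mean of 0.161 CPM. The upper limits of their 95% counting intervals were 0.178 to 0.441 CPM. Low transcription of AQP1 in this culture of HuCCT1 may be the reason. Reads missed in counting were not excluded, and the parental line was not analysed here. Protein was not measured in these data.

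With 3 libraries against 3 there are 10 splits, the real one included, which are too few for a share under 0.05. The real split gave 10711 called genes, 5347 higher, 5364 lower and 3279 at 2-fold, and the highest other split gave 0 for each, so 1 of the 10 splits gave as many genes in each count. Every other split mixes libraries of both clones, which puts the large difference between clones into the spread within groups. A count of 0 was therefore built in and does not test chance. For the epithelial list the real camera p was 3.69e-16 and the smallest of the other splits 7.39e-08, and for the mesenchymal list 6.23e-08 and 4.39e-05, with 1 split as small for each. The largest camera p of the other splits was 1.78e-05 for the epithelial list and 0.00202 for the mesenchymal list. Mixed splits still hold part of the difference between clones, so they give no chance level for these p. For the transcription factor list the real p was 0.0504 and the smallest other 0.022, with 2 splits as small.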
